A study of Bacteria with 15 samples.

How the data were processed

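Refuse of a landfill was sampled at 5 depths, 6, 12, 18, 24 and 30 m, each with 1 age of the refuse, and 3 samples per depth gave 15 arrays of genomic DNA. Per the labels, the samples came from 3 cores, and the labels do not say whether the replicate numbers stand for the cores. The replicate numbers were therefore not used to pair samples. The deposited table holds a linear intensity per probe and sample, rescaled by the authors in a way that neither the labels nor the table states. The labels name Cy5 in one field and Cy-3 in another, and image analysis, background handling and spot filter are not stated. The smallest intensity in the table was 1003.81. A blank was read as no signal, as was the value 0, which stands in place of blanks in 1 column, replicate 1 of 24 m. A final entry without a probe identifier, equal to the mean of that column, was left out. That left 38298 probes under 737 gene names, and probes sharing a gene name were taken as a family.

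Probes with a signal were counted per sample, and the Shannon index (natural log) was computed from the linear intensities. Both were tested by permutation (100000 draws) of the one-way F over the 5 depths and of Pearson and Spearman correlations with depth, two-sided, and each depth against 6 m by an exact permutation test. With 3 samples against 3 that test cannot go below 0.1. Benjamini-Hochberg adjustment was over the 2 measures. Composition was compared by Bray-Curtis distances of intensities scaled to the sample total, with a permutation test of the share of variation between depths. The smallest p that 100000 permutations can give is 1e-05.

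A family's value was the sum of its detected probes as a share of the sample total, on the log2 scale. A family without a signal in a sample was set to the lowest single-probe intensity of that sample before scaling. Families with at least 5 probes were tested, 466 in all with 37762 probes. limma 3.58.1 (lmFit, eBayes with an intensity trend) gave a moderated F over the 5 depths, a slope on depth, printed as the fitted log2 change from 6 to 30 m, and each depth against 6 m. Adjusted p values are Benjamini-Hochberg over all families of a test, with a threshold of 0.05. Single probes were tested the same way if they had a signal in at least 12 samples and at every depth. Probes specific to a depth had a signal in all 3 of its samples and in no other.

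Fixed lists of genes for 34 functions were summed per sample and tested by permutation of the F and of the slope, with adjustment over the lists. Names were matched without regard to case, spaces or joining marks, so families whose names carry a suffix may be missing from a list. One entry, mer, was taken out of the methanogenesis list after the names were seen, since the table uses it for mercury resistance. The 16 categories of the array and its sub-categories, phyla and domains with at least 50 probes, and genus groups within the mcrA signal were tested the same way. The set test camera was run on the slopes, with a preset and with an estimated correlation between families. Families were named by a fixed rule. It took the 10 largest rises and 10 largest falls among those past the threshold for the depth trend, up to 3 members of each list with the smallest F-test p, and the 3 largest rises and 3 largest falls of each depth against 6 m. Several marker genes were always named, from mcrA to ArsC, of which merA was not in the table under that name. The rule named 120 families.

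These choices, the lists and the alternatives were set before the data were examined, except the alternatives named as added. The alternatives were no division by the sample total, the mean signal of the detected probes, the number of detected probes, other minimum numbers of probes, eBayes without the trend, replicate number as a block, other rules of detection, presence or absence in the distances, and leaving out each sample. Added later were shares over probes detected in all samples, removal of a loess relation (span 0.75) between share and mean signal per probe, all 4 divisions along depth into shallower and deeper samples, and distances over the same number of brightest probes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.

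On simulated data with the spread of these families and 100 of 466 changed, the trend test recovered 51%, 86% and 95% of changes of 0.5, 1 and 2 log2, with 3.77%, 5.49% and 3.06% false among its calls. The test of 24 m against 6 m recovered 47%, 86% and 96%. The families were simulated as independent of each other, without shared shifts or samples lacking a signal, so these rates may not hold for the real families. In simulated values shifted by 2 SD, the permutation F found 64% and the slope 82%, against 3% and 5% in values without a shift. The number of arrays limits the precision, and p values cover the spread between samples only, not errors shared by all arrays.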

Results

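The samples were refuse drilled from a sanitary landfill at 5 depths, with 3 samples per depth and 15 in all. Depth and age of the refuse went together, so depth below stands for both. Refuse at 6 m was 2 years old, at 12 m 4 years, at 18 m 6 years, at 24 m 8 years and at 30 m 10 years. DNA of the microbes washed from the refuse was hybridised to a GeoChip, an array of probes for genes of known function. The table held 38298 probes under 737 gene names, here called gene families. Each sample gave a signal at 14540 to 25144 probes, and its signals summed to 134.8 to 170.4 mega-units of intensity. The sum averaged 165.7 ± 4.5 mega-units at 6 m and 140.8 ± 5.3 at 30 m (SD, n = 3). The mean signal of a detected probe was 8933 ± 233 at 6 m, 6560 ± 538 at 24 m and 7119 ± 729 at 30 m (SD, n = 3). The number of samples limits the precision of every value.

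Whether deep refuse holds a more diverse set of microbial functional genes is the question named in the series title. Refuse from 24 m had the highest mean number of detected probes, 22783 ± 2464, against 18558 ± 772 at 6 m (SD, n = 3), a ratio of 1.23. The means at the other depths were 17563 ± 1986 at 12 m, 18243 ± 4256 at 18 m and 19947 ± 2602 at 30 m. The Shannon index, which grows with the number of genes and the evenness of their signals, was also highest there. It was 9.76 ± 0.10 at 24 m and 9.64 ± 0.13 at 30 m against 9.53 ± 0.03 at 6 m, 9.47 ± 0.11 at 12 m and 9.49 ± 0.22 at 18 m. Neither difference among the 5 depths exceeded what the spread between samples allows. The permutation p was 0.202 for probes detected (F = 1.81) and 0.115 for the Shannon index (F = 2.53), and 0.202 for both after adjustment over the pair. Across the 15 samples, probes detected had a Pearson r of 0.396 with depth (permutation p = 0.144, adjusted 0.144) and a Spearman rho of 0.382 (p = 0.168, adjusted 0.168). The Shannon index had an r of 0.478 (permutation p = 0.0721, adjusted 0.144) and a rho of 0.535 (p = 0.0447, adjusted 0.0895). Leaving out a pair of the samples farthest from the median depth gave r of 0.296 to 0.562 for probes and 0.383 to 0.589 for Shannon. Exact two-sided permutation tests against 6 m gave p of 0.7, 0.9, 0.1 and 0.6 for probes and 0.7, 0.8, 0.1 and 0.2 for Shannon at 12, 18, 24 and 30 m, where 3 samples against 3 cannot go below 0.1. Single samples decided both 5-depth tests. Without 18 m replicate 2 the permutation p was 0.0334 for probes and 0.0112 for Shannon. The Shannon correlation passed without 18 m replicate 3 (p = 0.0432) or 30 m replicate 3 (p = 0.0423). Counting only probes seen in 2 of the 3 samples of a depth, a rule that itself uses the depths, gave p of 0.00648 for probes, and 0.00243 (F) and 0.0429 (r) for Shannon.

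**Figure D1:**
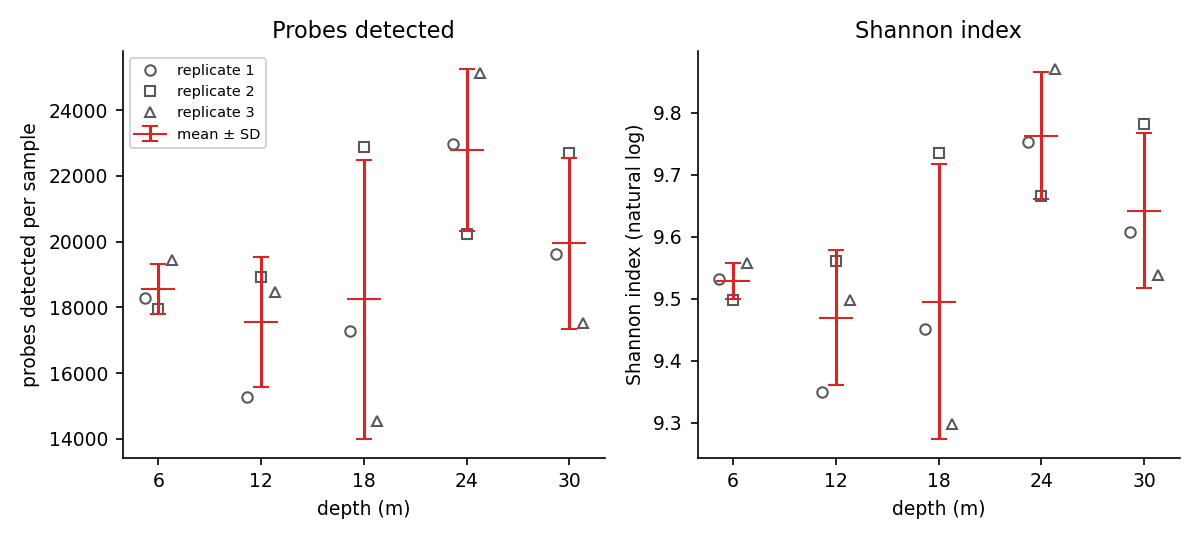
Number of probes detected (left) and Shannon index (right, natural log) against depth in m, with 1 open symbol per sample and red bars for the mean ± SD of 3 samples. The mean is highest at 24 m in both panels, and the 3 samples of 18 m span 14540 to 22893 probes.

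The make-up of the gene pool differed between depths, though not between all neighbouring ones by distance. Pooled over depths, samples of the same depth were closer to each other, with a Bray-Curtis distance of 26.0 ± 5.5% over 15 pairs, than samples of different depths, at 29.3 ± 6.7% over 90 pairs (SD). Samples of 6 m lay 20.6% from those of 12 m, against 21.5% within 6 m and 21.9% within 12 m, and 24 m lay 28.8% from 30 m, against 30.9% and 27.3% within them. Differences between the 5 depths held 42.7% of the variation in composition (permutation test on the distances, pseudo-F = 1.86, p = 0.0154), and presence or absence alone gave 36.9% (p = 0.0244). Any grouping of 15 samples into 5 groups holds a part of the variation, so these shares overstate what goes with depth. At the level of phyla, the share of signal from Ascomycota, the phylum of most moulds and yeasts, rose from 5.90 ± 0.37% at 6 m to 6.93 ± 0.34% at 30 m (SD, n = 3; fitted log2 change 0.25, adjusted permutation p = 0.0244). Eukaryota as a domain rose from 8.29 ± 0.54% to 9.56 ± 0.51% (0.23, adjusted permutation p = 0.00896). Bacteria fell from 87.7 ± 0.38% to 86.6 ± 0.52% (-0.02, adjusted permutation p = 0.0278). Archaea were at -0.13 (adjusted permutation p = 0.108). Without division by the sample total the Eukaryota value turned to -0.01 and Ascomycota was at 0.01 (adjusted permutation p = 0.854), while Bacteria fell by 0.26 and Archaea by 0.37 (0.00122). Of 20 phyla Ascomycota alone passed by share, and without the division 17 others did, all falling. The Ascomycota call also ended with a replicate block (0.0522) and by number of detected probes (0.0827), as did that of Bacteria by number (0.0717). Proteobacteria were at 39.6 ± 0.68% and 40.1 ± 0.93%, Actinobacteria at 18.7 ± 1.2% and 18.8 ± 0.44%. Firmicutes, which hold many fermenters, were at 8.53 ± 0.81% and 7.67 ± 0.49% (6 and 30 m). The Ascomycota call ended without 6 m replicate 1 (adjusted permutation p = 0.0924), 12 m replicate 1 (0.0514), 12 m replicate 2 (0.0514), 12 m replicate 3 (0.0518) or 30 m replicate 1 (0.0908). That of Bacteria ended without 6 m replicate 1 (0.0706), 30 m replicate 1 (0.0928) or 30 m replicate 3 (0.0734).

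**Figure D2:**
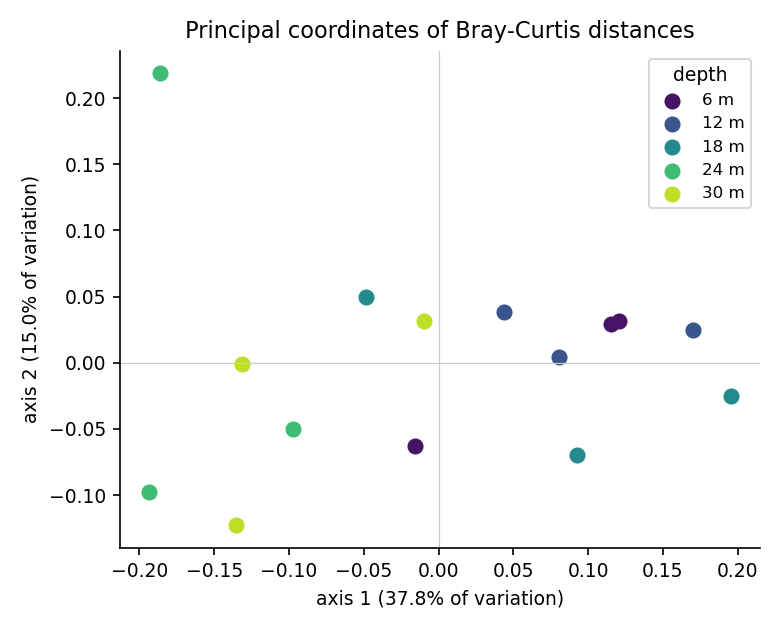
Principal coordinates of the Bray-Curtis distances between the 15 samples, 1 point per sample coloured by depth in m; the axes hold 37.8% and 14.97% of the variation. All 6 samples of 24 and 30 m lie below 0 on the first axis, together with 1 sample of 6 m and 1 of 18 m.

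Along depth, more families gained than lost share of the signal. Of 466 families with at least 5 probes, 67 rose and 18 fell with depth (limma, adjusted p under 0.05; 159 passed unadjusted). Another test found that 60 differed among the 5 depths (137 unadjusted), 46 of them among the 85 with a trend. The 18 that fell held 4 of the 7 sulfur oxidation families. Every share below is relative to the sample total. Without that division the median fitted change of all 466 families moved from 0.12 to -0.12. The split went from 78.8% rising to 15.9% (18 rising, 95 falling), with 36 of the 85 calls kept. By mean signal of the detected probes most families went down together, with a median of -0.39 over the 466. On that measure 0.588% of 170 calls were rises and 54 of the 67 had the opposite sign, which counts this shared shift. The sign was opposite in 24 of the 35 rising families named below, the others being pabA, nep, siderophore_transporter, arsA_fungi, nicdehydr, coat_Carmovirus, merT, dehH, ohbAB, lip and dnaK. The number of detected probes as a share gave 13 calls, 61.5% of them rises. Families with dim probes gained most, with a Spearman rho of -0.56 between mean signal and fitted change across the 466 families, which are not independent replicates. With that relation removed in each sample 14 families were called (64.3% rising), 11 of them among the 85. With shares over probes detected in all 15 samples 47 of 404 were called (78.7% rising), 23 of them among the 85, and 15 of the 58 rises with such probes and 2 of the 18 falls had the opposite sign. Single samples also moved the trend count. It was 24 without 30 m replicate 2, 27 without 30 m replicate 1, 49 without 6 m replicate 2, 50 without 6 m replicate 1, 50 without 24 m replicate 1 and 55 without 24 m replicate 2. The 5-depth count of 60 was 0 without 24 m replicate 1, 13 without 30 m replicate 2, 13 without 6 m replicate 1, 15 without 6 m replicate 2, 15 without 12 m replicate 1, 15 without 24 m replicate 3, 28 without 30 m replicate 1, 29 without 18 m replicate 1, 31 without 24 m replicate 2, 32 without 12 m replicate 3 and 95 without 18 m replicate 2.

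The 10 families with the largest rises were small ones, of 6 to 19 probes. Among them pabA, for a subunit of the enzyme making p-aminobenzoate on the way to folate, had a signal in 1 of the 9 samples of 6 to 18 m and in all 6 of 24 and 30 m. Its fitted log2 change of 2.93 ± 0.75 SE (limma adjusted p = 0.0179) rests on the lowest intensity of a sample, put in place of no signal in 8 samples, so its size is not known. The same was done in 2 samples for nep, and in 1 each for arsA_fungi, coat_Carmovirus and ArsA, which makes 4 of the 85 families with a trend. For nep, of necrosis-inducing proteins of plant pathogens, the rise was 2.36 ± 0.73, and for siderophore_transporter, of iron uptake by fungi, 2.22 ± 0.58, from 0.00520 ± 0.0028% to 0.0166 ± 0.0044% of the signal at 6 and 30 m (SD, n = 3). arsA_fungi, for an arsenite pump ATPase, rose by 2.00 ± 0.64, and merT, for a mercury transporter of the membrane, by 1.62 ± 0.46. Of families for breakdown of organic compounds, nicdehydr, for a nicotine dehydrogenase, rose by 1.68 ± 0.57, dehH, for a haloacid dehalogenase, by 1.56 ± 0.45, mhpC, for ring-cleavage product hydrolysis, by 1.48 ± 0.43, and ohbAB, for ortho-halobenzoate dioxygenase, by 1.30 ± 0.36. coat_Carmovirus, for the coat protein of a genus of plant viruses, rose by 1.67 ± 0.56. Adjusted p values of these 10 ran from 0.0179 to 0.0455. All 10 were above the 6 m mean in 6 of the 6 samples of 24 and 30 m, which follows in part from their choice as the largest rises. Mean signal per detected probe was at 0.25 to 0.49 for the 5 others with a signal in every sample and at -0.24 for mhpC, and passed for none of these (limma adjusted p of 0.104 to 0.442). For pabA, nep, arsA_fungi and coat_Carmovirus that measure too holds the lowest intensity in place of no signal.

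The 10 with the largest falls included 3 sulfur oxidation families, soxV, soxA and sqr. The first, soxV, went from 0.0860 ± 0.011% to 0.0480 ± 0.028% at 6 and 30 m (SD, n = 3; -0.94 ± 0.29 SE, limma adjusted p = 0.0352). tfdB, for chlorophenol hydroxylase, fell by 0.91 ± 0.26, cbdA, for halobenzoate dioxygenase, by 0.73 ± 0.23, and arhA, of heterocyclic aromatic breakdown, by 0.43 ± 0.13. pel_CDeg, a pectate lyase family, fell by 0.75 ± 0.18, and papC, for the outer membrane usher of pili, by 0.50 ± 0.16. nirA, for assimilatory nitrite reductase, fell by 0.44 ± 0.14. hyaluronidase, for cleavage of hyaluronic acid, fell by 0.47 ± 0.12 and turned to 0.09 over probes detected in all samples. Adjusted p values of the 10 ran from 0.0172 to 0.0412. Each was below the 6 m mean in 6 of the 6 deep samples, or in 5 for cbdA, hyaluronidase and sqr, which follows in part from their choice on these samples. Each was also lower without division by the sample total, as it had to be, since that lowers every family by 0.24.

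**Figure D3:**
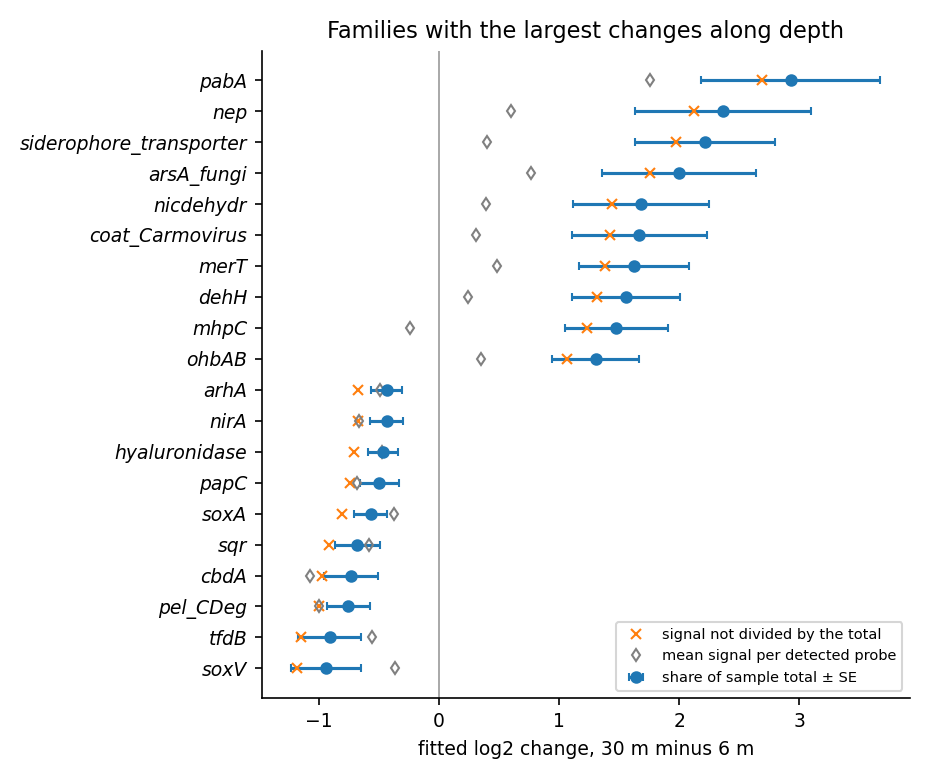
Fitted log2 change of 30 m minus 6 m for the 10 families with the largest rises and the 10 with the largest falls among those past the threshold: filled circles with SE bars for the share of the sample total, crosses for the signal not divided by it, open diamonds for the mean signal per detected probe. From -0.94 for soxV to 2.93 for pabA, where 8 samples hold the lowest intensity in place of no signal, the sign is the same in all 3 except for mhpC, whose mean signal per probe was at -0.24. The crosses lie 0.24 below the circles for every family, so their sign could not change here.

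Sulfur oxidation genes fell as a group. Their summed share went from 1.497 ± 0.052% at 6 m to 1.28 ± 0.12% at 24 m and 1.21 ± 0.06% at 30 m (SD, n = 3; fitted log2 change -0.36, adjusted permutation p = 0.0116, and 0.0324 for the 5 depths). Of 7 measured families 4 fell, over all families and adjusted over the list alone, and the other 3 did not pass. The family sqr, which oxidises sulfide to sulfur, went from 0.332 ± 0.025% to 0.211 ± 0.064% (-0.68 ± 0.19 SE, limma adjusted p = 0.0275). soxA, a cytochrome that binds thiosulfate, fell by 0.57 ± 0.14 (limma adjusted p = 0.0172), soxB, the sulfate-releasing hydrolase of that pathway, by 0.40 ± 0.10 (0.0179), and soxV, for electron transfer to it, by 0.94. With the relation to signal level removed 0 of the 7 passed (limma), as these changes shrank more than their SE, in that order to -0.54 ± 0.19 (0.105), -0.47 ± 0.13 (0.0538), -0.29 ± 0.08 (0.0538) and -0.88 ± 0.29 (0.0849). The list's slope call stood without each of the 15 samples, with an adjusted permutation p of at most 0.0306. Its call over the 5 depths ended at least without 6 m replicate 1, 24 m replicate 1 or 3, or 30 m replicate 2. That call also ended with a replicate block (adjusted permutation p = 0.0546) and by number of detected probes (0.103). The set test camera, which compares the slope statistics of a list with those of all other families, gave sulfur oxidation an adjusted p of 0.000496 with a preset correlation. No other list of 31 passed camera, and with an estimated correlation the adjusted p was 0.111 and 0 lists passed. Without division by the total, which lowers every list by 0.24, this list fell by 0.60 (adjusted permutation p = 0.00017), and by number of detected probes by 0.32 (0.0216). Over the 76 of its probes detected in all samples the list was at -0.06 (permutation p = 0.272), and soxA turned to 0.01.

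**Figure D4:**
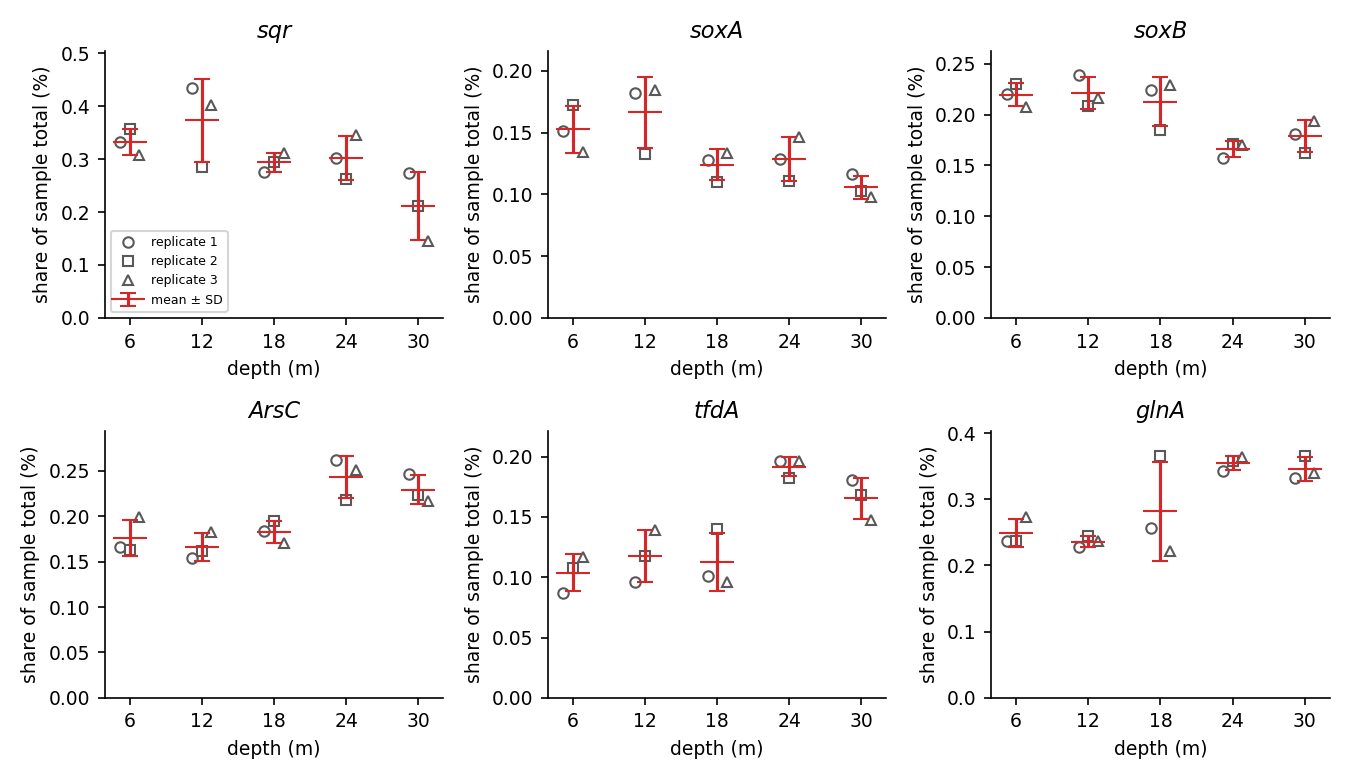
Share of the sample total (%) against depth in m for the sulfur oxidation families sqr, soxA and soxB and for ArsC, tfdA and glnA, with 1 open symbol per sample and red bars for the mean ± SD of 3 samples. soxB is lower and tfdA higher in each sample of 24 and 30 m than the mean at 6 m, of 0.219% and 0.104%, while over probes detected in all samples tfdA, ArsC and soxA turned the other way (-0.20, -0.07 and 0.01).

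Of genes against toxic metals 4 lists gained share, but the array category metal resistance as a whole was at 0.02 (adjusted permutation p = 0.779), or -0.22 without division by the total. The arsenic list rose from 0.326 ± 0.022% to 0.402 ± 0.028% at 6 and 30 m (SD, n = 3; 0.42, adjusted permutation p = 0.0176; 0.18 and 0.22 without division by the total). Of its 5 families 2 rose, also over the list alone: ArsC, the arsenate reductase (0.53 ± 0.12 SE, limma adjusted p = 0.0147), and arsB, the arsenite pump (0.68 ± 0.22, 0.0412), and both turned over probes detected in all samples (-0.07 and -0.15). ArsA, the ATPase of that pump, was at 1.00 ± 0.62 (0.27). The tellurium, silver and lead list rose by 0.48 (0.0335; 0.24 and 0.257 without the division), with 2 of 9 families, or 6 adjusted over the list alone. TerC, of tellurium resistance, rose by 0.59 ± 0.15 (0.0179) and turned to -0.28 over probes detected in all samples. In the same list TehB, a tellurite methyltransferase, was at 0.54 ± 0.23 (0.107), and silP, a silver efflux pump, at 1.04 ± 0.42 (0.0829). The cadmium, cobalt, zinc and nickel list rose by 0.24 (0.0199) and was at -0.0039 without division by the total. Its czcD, a cation efflux carrier, rose by 0.52 ± 0.15 (0.0282) as 1 of 10 families, while CadA, a cadmium ATPase, was at 0.26 ± 0.11 (0.102) and CorC at 0.94 ± 0.64 (0.303). ChrA, the chromate efflux carrier and the 1 family of the chromium list, rose by 0.22 ± 0.07 (0.0322), but was at -0.02 without division by the total and over probes detected in all samples. In the mercury list, at 0.12 (0.323), merT rose as 1 of 4 families, also over the list alone. There merP, the periplasmic binding protein, was at 0.32 ± 0.18 (0.213) and mer at 0.02 ± 0.10 (0.887). The copper list, at 0.22 (0.138), had 0 of 3 families past the threshold (limma; 0 adjusted over the list alone, 1 unadjusted). They were CopA, a copper ATPase, at 0.20 ± 0.11, CueO, a copper oxidase, at 1.28 ± 0.51, and CusA, an efflux pump, at -0.06 ± 0.37.

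Of the stress response lists 3 gained share, though none of the 3 passed without division by the total. The oxidative and oxygen stress list rose from 1.24 ± 0.08% to 1.53 ± 0.14% (SD, n = 3; 0.41, adjusted permutation p = 0.0248; 0.17 and 0.295 without the division), with 5 of 13 families rising, or 6 adjusted over the list alone. fnr, the oxygen-sensing regulator, rose by 0.53 ± 0.13 SE (limma adjusted p = 0.0172; -0.01 with the relation to signal level removed). Also rising were ahpC, an alkyl hydroperoxide reductase, by 0.38 ± 0.11 (0.0282), and narI, a subunit of respiratory nitrate reductase, by 0.36 ± 0.10 (0.0292). Oxygen sensing and nitrate respiration thus share this list with peroxide removal, so its rise is not one of oxidative stress alone. As array sub-categories, oxygen stress passed by slope (0.47, adjusted permutation p = 0.0186, and 0.313 without the division) and oxygen limitation did not (0.23, 0.0577). Both passed the F over the 5 depths (adjusted permutation p = 0.0473 for each), though not without the division (0.334 and 0.488). A difference between their slopes was not tested. The heat and cold shock list rose by 0.24 (0.0393; 0.0041 and 0.993 without the division), with 2 of 6 families. They were the chaperone gene dnaK by 0.91 ± 0.22 (0.0172) and grpE, its exchange factor, by 0.62 ± 0.20 (0.0412; -0.01 over probes detected in all samples). Another chaperone, groEL, was at 0.12 ± 0.16 (0.607). Among sigma factors, which direct RNA polymerase to promoters, 2 of 4 families rose, or 3 adjusted over the list alone. They were sigma_32, of heat shock, by 0.65 ± 0.17 (0.0213) and sigma_38, of stationary phase, by 0.55 ± 0.17 (0.0322; -0.20 over probes detected in all samples). For sigma_70, the housekeeping factor, the value was 0.44 ± 0.16 (0.055), and for the list 0.27 (0.081). The nitrogen and phosphate limitation list rose by 0.36 (0.0248; 0.12 and 0.396 without the division), with 1 of 8 families, or 3 over the list alone. That family, glnA for glutamine synthetase, went from 0.249 ± 0.021% to 0.346 ± 0.018% (0.62 ± 0.13, 0.0147), while pstS, for phosphate uptake, was at 0.49 ± 0.24 (0.159) and the regulator glnR at 0.34 ± 0.61 (0.706). In the osmotic stress list, at 0.25 (0.138), proX, for uptake of glycine betaine, rose by 0.84 ± 0.20 (0.0172) as 1 of 3 families, with proV at 0.15 ± 0.16 and opuE at 0.52 ± 0.28. Cytochromes and hydrogenases of energy metabolism rose by 0.24 as a list (0.0116), and were at -0.00068 without division by the total. Of the 5 families cytochrome rose by 0.29 ± 0.07 (0.0172), with cytochrome_c at 0.29 ± 0.17 and P450 at 0.13 ± 0.24.

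The lists for aromatic pollutants and antibiotic resistance gained share as well. The aromatic pollutant list rose from 3.59 ± 0.18% to 4.00 ± 0.17% (SD, n = 3; 0.22, adjusted permutation p = 0.0335), and was at -0.02 without division by the total. Of 41 families 9 rose and 1 fell, or 11 and 1 adjusted over the list alone. The gene tfdA, which opens the breakdown of a chlorinated herbicide, went from 0.104 ± 0.016% to 0.165 ± 0.017% (0.83 ± 0.18 SE, limma adjusted p = 0.0147; -0.20 over probes detected in all samples). tftH, of chlorinated phenol breakdown, rose by 0.77 ± 0.14 (0.0147) and alkK, an acyl-CoA synthetase of alkane breakdown, by 0.42 ± 0.11 (0.0179; -0.01 over probes detected in all samples). In the chlorinated solvent list, at 0.13 (0.182), 3 of 8 families rose, also over the list alone: dehH, dehH109 (0.68 ± 0.19, 0.0277), another dehalogenase, and linB, a haloalkane dehalogenase (0.39 ± 0.13, 0.0455). The antibiotic resistance list rose by 0.29 (0.0335), and was at 0.05 (adjusted permutation p = 0.81) without division by the total. Its families had a median of 0.03, and 1 of 10 rose: SMR_antibiotics, small multidrug efflux pumps, went from 0.210 ± 0.026% to 0.309 ± 0.035% (0.74 ± 0.16, 0.0147). In that list MFS_antibiotic, another class of pumps, was at 0.40 ± 0.15 (0.0718) and B_lactamase_C, which opens beta-lactam rings, at 0.31 ± 0.12 (0.075).

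Of the lists for carbon breakdown and for methane 0 passed (permutation test of the slope; 1 unadjusted). Without division by the total methane oxidation (-0.32, adjusted permutation p = 0.00115), cellulose (-0.28, 0.00147), hemicellulose (-0.27, 0.000486), starch (-0.38, 0.00167), chitin (-0.26, 0.00372), pectin (-0.28, 0.00126) and lignin (-0.27, 0.000425) all fell. That setting lowers every list by 0.24, so most of each of these falls is the lower total signal shared by all lists. The family mcrA, the marker of methane formation, was at 0.195 ± 0.039% at 6 m and 0.249 ± 0.0097% at 30 m (SD, n = 3; 0.38 ± 0.13 SE, limma adjusted p = 0.055), above the 6 m mean in 6 of the 6 deep samples. It passed when adjusted over the list alone, as 1 of 2 families. The other, hdrB for heterodisulfide reductase, was at -0.34 ± 0.38. The methanogenesis list was at 0.34 (0.0603), at 0.10 (0.715) without division by the total, and turned to -0.02 (0.863) by number of detected probes. Within the mcrA signal, the share of methylotrophic genera was 1.19 ± 0.14% at 6 m and 2.34 ± 0.99% at 30 m (adjusted permutation p = 0.192). These genera had 4 probes, of which 1.00 gave a signal on average at 6 m and 1.67 at 30 m. That of hydrogenotrophic genera, with 16 probes, was 16.8 ± 1.8% and 15.4 ± 2.1% (0.97), and that of acetoclastic or versatile genera, with 2 probes, 5.04 ± 0.63% and 4.10 ± 1.2% (0.97). Most of the mcrA signal, 76.9 ± 2.3% at 6 m and 78.2 ± 3.3% at 30 m, came from 71 probes of no listed genus, so these shares do not give the make-up of the methanogens. The methane oxidation list did not pass (-0.08, 0.214), and limma called 0 of its 3 families (0 unadjusted): the monooxygenase genes pmoA (-0.10 ± 0.10) and mmoX (0.12 ± 0.22), and mdh (-0.15 ± 0.17). For acetogenesis and carbon fixation the list was at -0.06 (0.0614), but passed without the division (-0.30, 0.00017), by number (-0.08, 0.0216) and with a replicate block (0.049), with 1 of 9 families falling, or 0 adjusted over the list alone (limma; 2 unadjusted). It was aclB, ATP citrate lyase of the reverse citric acid cycle, which fell by 0.37 ± 0.12 (0.0462), though its number of detected probes was at 0.03. FTHFS, of acetogens, was at -0.08 ± 0.06, CODH at -0.07 ± 0.06, rubisco at -0.05 ± 0.08, oorA at -0.21 ± 0.20 and MCM at 0.46 ± 0.19. Of cellulose, hemicellulose, starch and chitin families 0 passed (limma; 0 over each list alone; 2, 0, 1 and 0 unadjusted). Their values were 0.26 ± 0.11 for exoglucanase, -0.11 ± 0.09 for cellobiase, -0.26 ± 0.11 for CDH, 0.03 ± 0.10 for xylanase, -0.12 ± 0.08 for mannanase and -0.17 ± 0.10 for ara_fungi, a fungal arabinofuranosidase. For starch they were -0.37 ± 0.13 for nplT, -0.16 ± 0.10 for cda and -0.16 ± 0.09 for glucoamylase, and for chitin -0.02 ± 0.06 for endochitinase, -0.07 ± 0.07 for acetylglucosaminidase and 0.81 ± 0.51 for chitin_deacetylase_fungi. These lists were at -0.04 (0.345), -0.03 (0.336), -0.14 (0.105) and -0.02 (0.688). Pectin lyase and pectinase families went both ways, with 3 of 9 rising and 2 falling (5 and 2 over the list alone) and a list value of -0.04 (0.388), while the median family was at 0.41. The family pectinase rose by 0.56 ± 0.16 (0.0282) and exopolygalacturonase_fungi by 0.55 ± 0.12 (0.0147), against the fall of pel_CDeg. In the lignin and aromatic carbon list, at -0.03 (0.336), lip, lignin peroxidase, rose by 0.87 ± 0.20 (0.0151) as 1 of 12 families, also over the list alone, with Ligninase at 0.86 ± 0.31 (0.0616) and vdh, of vanillin breakdown, at -0.20 ± 0.09 (0.0982).

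**Figure D5:**
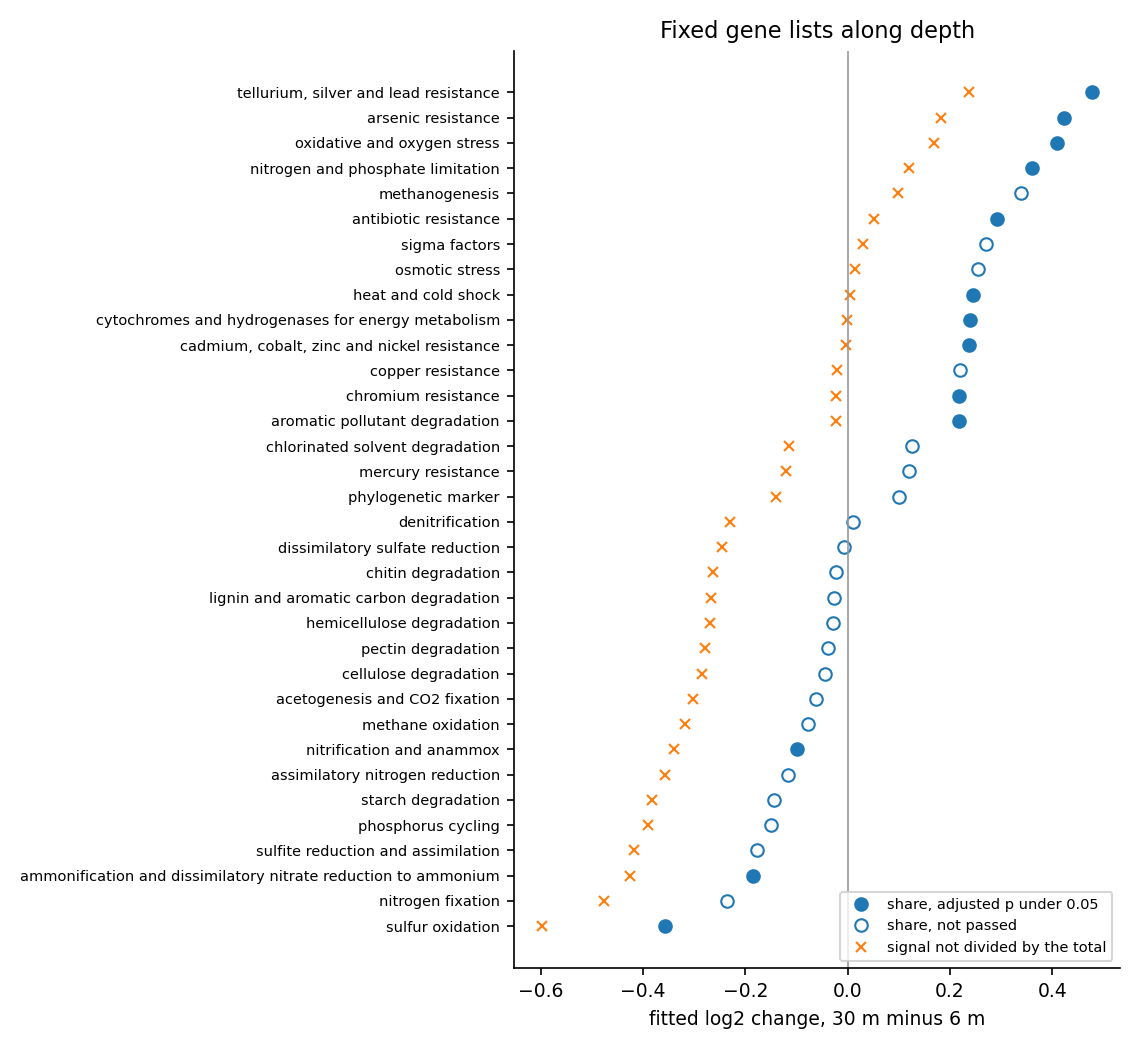
Fitted log2 change of 30 m minus 6 m for the 34 gene lists: filled circles for shares that passed (adjusted permutation p under 0.05), open circles for those that did not, crosses for signals not divided by the sample total. Shares of 10 lists rose and of 3 fell; without the division 0 of the 10 passed, 4 of them (cytochromes, chromium, aromatic pollutants, and cadmium to nickel) lay at 0 or below, and 17 lists passed, all falling.

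In the nitrogen cycle the ammonification list fell and the denitrification list did not pass. The ammonification and nitrate ammonification list went from 2.84 ± 0.15% to 2.56 ± 0.10% (SD, n = 3; -0.19, adjusted permutation p = 0.0335). Of its 4 families 2 fell, also over the list alone: ureC, a urease subunit, by 0.19 ± 0.06 SE (limma adjusted p = 0.0344) and gdh, glutamate dehydrogenase, by 0.37 ± 0.12 (0.0412). The nitrate reductase gene napA was at 0.11 ± 0.10 and nrfA, for nitrite reduction to ammonium, at -0.09 ± 0.08. The nitrification and anammox list fell by 0.10 (0.0394) while 0 of its 3 families passed (limma; 0 over the list alone, 0 unadjusted). They were amoA, of ammonia oxidation, at -0.09 ± 0.05, hao, of hydroxylamine oxidation, at -0.27 ± 0.18 and hzo, of anammox, at -0.88 ± 0.43. Denitrification had 0 of 6 (limma; 0 over the list alone, 0 unadjusted) and a list value of 0.01 (0.901), turned to -0.23 (0.0396) without division by the total. Its families were narG at -0.03 ± 0.09, nirS at 0.16 ± 0.09, nirK at -0.10 ± 0.06, NirK at -0.36 ± 0.19, norB at 0.17 ± 0.12 and nosZ, for nitrous oxide reduction, at 0.02 ± 0.10. The array second sub-category denitrifying, which holds nirK and NirK alone, fell by 0.14 (adjusted permutation p = 0.0389) but turned to 0.0033 by number of detected probes. That call ended without 6 m replicate 1 (0.0713) or 2 (0.0932), 12 m replicate 3 (0.0582), 18 m replicate 2 (0.0545), 24 m replicate 3 (0.0666) or 30 m replicate 2 (0.119). nifH, for nitrogen fixation, was at -0.24 ± 0.12 (0.18; list value -0.24, 0.157), and 0 passed unadjusted. Assimilatory reduction had nirA falling as 1 of 5 families, also over the list alone, nasA at 0.02 ± 0.10, nirB at -0.11 ± 0.14 and the list at -0.12 (0.194). Dissimilatory sulfate reduction had 0 of 3 (limma; 0 over the list alone, 0 unadjusted) and a list value of -0.01 (0.837), with dsrA at -0.05 ± 0.05, dsrB at 0.04 ± 0.07 and AprA at 0.19 ± 0.11. Sulfite reduction and assimilation (limma, 0 of 3 and 0 unadjusted; list -0.18, 0.292) had CysJ at -0.25 ± 0.20, CysI at -0.00 ± 0.12 and sir at -0.13 ± 0.10. Phosphorus cycling (limma, 0 of 3 and 2 unadjusted; list -0.15, 0.103) had ppx, an exopolyphosphatase, at -0.20 ± 0.08, ppk, a polyphosphate kinase, at 0.01 ± 0.07 and phytase at -0.20 ± 0.09. gyrB, a phylogenetic marker, was at 0.10 ± 0.06 (0.242; list value 0.10, 0.101).

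Of all 34 lists, 13 had a slope on depth past the threshold and 7 differed among the 5 depths. These 7 were sulfur oxidation, arsenic, cadmium to nickel, oxidative and oxygen stress, heat shock, nitrogen and phosphate limitation, and cytochromes. None of the 7 calls over the 5 depths held by number of detected probes (lowest adjusted permutation p = 0.103) or with a replicate block (lowest 0.0546). The list value and the median of its families had opposite signs for pectin, chitin (median 0.03), lignin (0.01), denitrification (-0.0044) and sulfate reduction (0.04). By number of detected probes the slope no longer passed for tellurium (adjusted permutation p = 0.107), antibiotics (0.105), aromatic pollutants (0.125), heat shock (0.202), nitrogen and phosphate limitation (0.105) and cytochromes (0.115). It passed by number, though not by share, for acetogenesis (0.0216), chlorinated solvents (0.0292) and phosphorus (0.0497). Heat shock also lost its call with a replicate block (0.0557). Without division by the total every list is lower by 0.24, and 17 passed, all falling. With 1 sample left out the count of slopes fell to 5 (30 m replicate 2), 7 (30 m replicate 1), 7 (24 m replicate 1), 8 (6 m replicate 2) and 8 (12 m replicate 1). The slope calls of sulfur oxidation, arsenic, cadmium to nickel, chromium and cytochromes stood in all 15 refits. Those of oxidative and oxygen stress and of nitrogen and phosphate limitation ended without 30 m replicate 2 (adjusted p of 0.055 and 0.0564). Those of tellurium, antibiotics and aromatic pollutants ended without 6 m replicate 2 (0.0567), 12 m replicate 1 (0.0502), 24 m replicate 1 (0.0513), 30 m replicate 1 (0.0558) or 30 m replicate 2 (0.0622). Ammonification lost its call without 6 m replicate 2 (0.0567), 24 m replicate 1 (0.0513) or any 30 m sample (0.0558, 0.0832 and 0.0622). Heat shock lost it without 6 m replicate 1 (0.0678) or 2 (0.0567), 12 m replicate 1 (0.0607) or 2 (0.0604), 24 m replicate 1 (0.0616) or 2 (0.0533), or 30 m replicate 1 (0.0509) or 2 (0.0722). Nitrification lost it without 6 m replicate 1 (0.106) or 2 (0.0567), 12 m replicate 1 (0.0607) or 3 (0.0592), 18 m replicate 1 (0.0509) or 2 (0.0523), any 24 m sample (0.0632, 0.05 and 0.0603), or 30 m replicate 1 (0.0668) or 2 (0.0622). The 5-depth count of 7 was 0 without 6 m replicate 1, 24 m replicate 1, 24 m replicate 3 or 30 m replicate 2, 1 without 18 m replicate 1, 2 without 6 m replicate 2 or 30 m replicate 1, 3 without 12 m replicate 1, 12 m replicate 3 or 24 m replicate 2, 11 without 30 m replicate 3 and 13 without 18 m replicate 2.

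Against the shallowest refuse, calls were made at 24 m alone. There 35 families differed from 6 m, 27 higher and 8 lower (limma; 134 unadjusted), 25 of them among those with a depth trend. Highest were TerZ, of tellurium resistance, from 0.0113 ± 0.0042% at 6 m (SD, n = 3; log2 difference 1.89 ± 0.53 SE, limma adjusted p = 0.0472), sod_CuZn, a superoxide dismutase that removes oxygen radicals (1.03 ± 0.26, 0.0306), and TehB (0.92 ± 0.17, 0.0124). Lowest were fumarase_DiC4HB, of an archaeal carbon fixation cycle (-1.19 ± 0.26, 0.0185), 4Fe_4S_ferredoxin, an electron carrier (-0.85 ± 0.25, 0.048), and bglH, of beta-glucoside use (-0.66 ± 0.18, 0.0472). Against 6 m, limma called 0 families at 12 m (10 unadjusted), 0 at 18 m (9) and 0 at 30 m (106). Without division by the total it called 30 at 24 m and 61 at 30 m. A difference between these contrasts was not tested. The count at 24 m was 0 without 24 m replicate 1, 24 m replicate 3, 6 m replicate 1 or 6 m replicate 2. It was 15 without 12 m replicate 3, 16 without 12 m replicate 2, 17 without 30 m replicate 2, 18 without 30 m replicate 1, 19 without 18 m replicate 1 and 21 without 30 m replicate 3. The count at 30 m was 4 without 12 m replicate 1, 1 without 18 m replicate 1, 11 without 18 m replicate 2, 5 without 30 m replicate 1 and 7 without 6 m replicate 3.

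Single probes differed among depths as well. Among 12666 probes with a signal in at least 12 samples and at every depth, 285 differed among the 5 depths (limma; 3631 unadjusted). That count was 10 without 30 m replicate 1 or 30 m replicate 2, 15 without 30 m replicate 3, 16 without 12 m replicate 1, 22 without 24 m replicate 1, 24 without 18 m replicate 1, 31 without 6 m replicate 2, 36 without 6 m replicate 1, 46 without 24 m replicate 2, 61 without 18 m replicate 3, 77 without 12 m replicate 3, 158 without 12 m replicate 2 and 2756 without 18 m replicate 2. Probes seen in all 3 samples of 1 depth and in no other sample numbered 70 at 24 m, 10 at 30 m, 4 at 12 m, 2 at 6 m and 1 at 18 m, 87 in all. Of the 70 at 24 m, 20 belonged to carbon cycling, 11 to metal resistance and 8 to sulfur genes, and none of the 16 array categories was enriched (Fisher's exact test; lowest adjusted p = 0.503).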

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

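Probes detected in all samples and removal of the relation to signal level were tests chosen after the results were seen. The cause was not tested for any change below. Composition kept its call in every setting run, with 41.7% to 49.1% without single samples. Families differing among depths, 60 as reported, numbered 7 by mean signal, 1 by number of probes, 18 without the eBayes trend, 26 with a replicate block, 30 over probes detected in all samples, 3 with the signal level removed, and 0 to 95 without single samples. The 85 trends became 170, 13, 47 and 14 by mean signal, number, probes detected in all samples and signal level removed, and 24 to 126 without single samples. Rises (67) became 18 unscaled, 1, 8, 37 and 9 in those settings, and 18 to 99. Falls (18) became 95 unscaled, 169, 5, 10 and 5, 11 without the eBayes trend, 11 with a block, and 4 to 27. At 24 m against 6 m the 35 became 2 by number, 23 with no minimum of probes, 15 without the eBayes trend, 18 with a block, 4 over probes detected in all samples, 1 with the level removed, and 0 to 51. At 30 m the 0 became 61 unscaled, 5 over probes detected in all samples, and 0 to 11. Probes (285) became 2863 unscaled, 605 with a signal in at least 3 samples, 41 with a block, and 10 to 2756. Counting probes seen in 2 of 3 samples of a depth gave an F of 6.87 for probes and 8.65 for Shannon, and a Shannon r of 0.53. Without single samples, F ran from 0.888 to 4.14 and from 1.49 to 5.98, and r from 0.318 to 0.508 and from 0.399 to 0.549. Depth-specific probes (87) were 856 with 2 of 3 samples and 44 above the 25th percentile. Fixed lists by F (7) were 14 unscaled, 0 by number, 0 with a block, and 0 to 13; by trend (13) 1 and 0 with camera, preset and estimated, and 5 to 16. Array categories by F (6) were 1 by number, 0 with a block, and 2 to 8, and by trend (8) 4 to 10. Sub-categories by F (18) were 1 by number, 0 with a block, and 0 to 23, and by trend (22) 3 by number and 17 to 31. The second sub-categories were 2 unscaled and 0 to 1 by F, and by trend (2) 7 unscaled, 0 by number, and 0 to 6. Phyla were 14 unscaled by F, and by trend (1) 17 unscaled, 0 by number, 0 with a block, and 0 to 4. Domains were 2 unscaled and 0 to 2 by F, and by trend (2) 1 by number and 1 to 3. Named families that turned by mean signal, where the median family was at -0.39, were mhpC -0.24, exopolygalacturonase_fungi -0.47, pectinase -0.054, nirS -0.44, dsrB -0.44, ArsC -0.33, arsB -0.39, mer -0.64, czcD -0.29, ChrA -0.43, TerC -0.33, SMR_antibiotics -0.30, tfdA -0.29, tftH -0.25, alkK -0.40, dehH109 -0.40, linB -0.48, narI -0.37, fnr -0.30, ahpC -0.46, grpE -0.33, sigma_32 -0.21, sigma_38 -0.48, proX -0.23, proV -0.61, glnA -0.26, gyrB -0.50, cytochrome -0.36, cytochrome_c -0.64 and sod_CuZn -0.22. Over probes detected in all samples soxA 0.012, hyaluronidase 0.094, hzo 0.76, CysI 0.33, ArsC -0.068, arsB -0.15, mer -0.29, ChrA -0.020, TerC -0.28, tfdA -0.20, alkK -0.015, grpE -0.012 and sigma_38 -0.20 turned. By number aclB turned to 0.032, unscaled ChrA to -0.022, and with the level removed fnr to -0.0085. Of the 49 named families with a trend, 547 of 735 refits without a sample kept the call and 188 did not. Pooled over depths, samples with the same replicate number were no more alike than others (mean r -0.03 over 30 pairs against 0.01 over 60). Between 24 and 30 m, though, log2 signals of samples with the same number had r of 0.919, 0.904 and 0.810. Samples of different numbers at these depths had r of 0.711 to 0.853. Whether the numbers pair samples is therefore not known.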

Other observations

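Tests chosen only after the results were seen were those of total signal, of oxygen, of the choice of dividing depth, of the 24 m column and of other splits of the samples, and the alternatives over probes detected in all samples, with the signal level removed, and with the same number of brightest probes.

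Of the array's own 16 categories 8 had a slope on depth and 6 differed among the 5 depths. The array category metal resistance was not among the 8 (0.02, adjusted permutation p = 0.779). Genes for traits useful in soil, named soil_benifit on the array, rose from 1.59% to 1.90% of the signal (0.32, adjusted permutation p = 0.00304), and virulence genes from 0.914% to 1.081% (0.30, 0.00328), each without any 1 sample too, but without the division none of the 7 rising categories passed. There soil_benifit was at 0.08 (0.431), virulence at 0.06 (0.618), stress at 0.09 (0.618) and antibiotic resistance at 0.05 (0.826). By number of detected probes stress (0.063), antibiotic resistance (0.063), organic remediation (0.0681) and energy process (0.179) did not pass. Energy process genes rose by 0.23 (0.00731) but were at -0.0055 without division by the sample total. Stress genes rose from 4.52% to 5.27% (0.33, 0.0234), a call that ended without 30 m replicate 2 (0.0524). Fungal function genes rose from 3.71% to 4.27% (0.22, 0.0234) but were at -0.02 without the division, and their call ended without 30 m replicate 1 (0.0637). Organic remediation (0.21, 0.0255; -0.03 without the division) and antibiotic resistance genes (0.29, 0.0234) rose, though not without 30 m replicate 1 (0.0551 for both) or 30 m replicate 2 (0.0548 for both). As an array category, sulphur fell by 0.12 (0.0325), but not without 6 m replicate 1 (0.0686) or 2 (0.0561), 12 m replicate 3 (0.0509), 24 m replicate 1 (0.0534) or 2 (0.0501), or 30 m replicate 1 (0.0637) or 2 (0.0706). The count of 8 was 4 without 30 m replicate 1 or 30 m replicate 2. Of 56 sub-categories 22 had a slope and 18 differed among depths. All of the slopes but those of sulfide oxidation and ammonification were rises, and without the division the lowest adjusted permutation p of a rise was 0.114. The 18 were 0 without 6 m replicate 1 or 2, 18 m replicate 1, 24 m replicate 1, or 30 m replicate 1 or 2, and 0 with a replicate block. Sulfide oxidation fell from 0.605% to 0.453% (-0.46, 0.0129), while the array's sub-category sulphur oxidation did not pass (-0.15, 0.0528). The latter did pass by number of detected probes (-0.24, 0.0165) and without the division (-0.39, 0.00048). Ammonification fell (-0.24, 0.0169), and pilin (0.32, 0.0129) and nitrogen limitation (0.59, 0.0173) rose. These 4 slope calls stood in all 15 refits, but without the division pilin (0.08, 0.507) and nitrogen limitation (0.35, 0.114) did not pass, nor by number of detected probes did sulfide oxidation (0.0623), pilin (0.104) and nitrogen limitation (0.0623). At the second level 2 of 17 classes had a slope, kept in 14 and, for denitrifying, in 9 of the 15 refits.

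The families that rose and those that fell moved apart from the rest by a median of 0.56 and -0.51 log2. For the rises a lower total signal at depth stays open. The division adds the same 0.24 to every family, so their median without it, 0.39 (95% bootstrap interval 0.32 to 0.44), decides nothing. Of the 67 rises, 18 kept their call. For the falls this argues against the division as the cause, since raising every share by 0.24 cannot make a share fall. Without it all 18 falls kept their call, with a median of -0.68 (95% bootstrap interval -0.86 to -0.61). That adds no support, since every family is lower there by the same 0.24. More probes detected at depth stays open, since over probes detected in all samples 36.3% of the gap was left for rises (14.7% to 55.6%) and 32.1% for falls (9.79% to 76.5%). A compressed signal range, which lifts dim families, stays open too, with 55.0% (46.9% to 77.8%) and 63.8% (45.9% to 83.3%) left after its removal. A change of the community with depth and age of the refuse is untested and stays open beside them.

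The sulfur oxidation list fell with depth by 0.36. Of 10000 random lists of families of like signal, 0.1% had a median as low as -0.40. This does not exclude a compressed signal range. The random lists were drawn family by family, so they leave out correlation within a list, and the list was picked for its large fall. With an estimated correlation camera gave an adjusted p of 0.111. With the relation to signal level removed the median was -0.29 and 0 of the 7 families passed, so a compressed range stays open. More probes detected elsewhere stays open, since the -0.06 (permutation p = 0.272) over the list's 76 probes detected in all samples leaves out those seen in some samples only, while its own signal fell by 0.60 without the division and its detected probes went both ways, 225 at 6 m, 245 at 24 m and 202 at 30 m. Less oxygen in deeper refuse is a possible explanation that stays undecided, as methane oxidation, which also needs oxygen, did not pass by share (-0.08, adjusted permutation p = 0.214) and fell without the division (-0.32, 0.00115), where 17 lists did. Other lists with genes for oxidation went both ways by share: nitrification and anammox fell (-0.10, adjusted permutation p = 0.0394) and aromatic pollutant degradation rose (0.22, 0.0335).

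Samples of 24 and 30 m stood apart from those of 6, 12 and 18 m in composition, a division that accounted for 28.5% of the variation, against 5.77%, 15.4% and 11.5% for those before 12, 18 and 30 m and 20.6% for a line on depth. If the 15 samples are independent, the choice of the best division after seeing them was excluded as the cause (permutation p = 0.00084 over the best of 4). The p values of these divisions were not computed within replicate numbers. Whether the numbers pair samples of 24 and 30 m is not known, and if they do these p values may be too small. An unequal number of probes alone does not account for it, as 14540 brightest probes in each sample gave 28.6% (permutation p = 0.00036). Equal numbers leave the lower signals of samples with many probes in place. The mean signal was 5982 in 24 m replicate 3, with 25144 probes, and 10833 in 18 m replicate 3, with 14540. An effect that goes with more detected probes therefore stays open. The column stored with zeros was excluded as the whole cause, since without 24 m replicate 1 the value was 27.0% (permutation p = 0.0015). Total signal divided at the same place. It was 134.8 to 152.8 mega-units in the samples of 24 and 30 m and 156.6 to 170.4 in the others. A difference in signal level, a compressed signal range included, was not tested for this division and stays open. The authors' normalization, which is not stated and was not tested, stays open too. A change of the refuse community between 18 and 24 m is a hypothesis found and tested on the same data. It cannot be told apart from these. The Shannon index had its best division at the same place (42.6%, permutation p = 0.0341 over the best of 4), and the number of detected probes did not pass (30.9%, permutation p = 0.1).

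Other splits of the 15 samples into 5 groups of 3 tested how often chance gives as many calls. The real split alone, 1 of 101, reached the 60 families differing among depths (highest other 22). So it was for the 85 trends (highest other 2) and the 285 probes (highest other 53). Chance is unlikely by this test, which cannot go below 1 of 101. Single samples still carried much of these counts. The 60 were 0 without 24 m replicate 1, and the 85 were 24 without 30 m replicate 2. The 285 were 10 without 30 m replicate 1 or 30 m replicate 2. Chance cannot be excluded for the 87 probes specific to a depth, as 8 of 101 splits gave as many, the highest 159. For single depths against 6 m the 10 splits are too few: 24 m gave 35 families with a highest other of 1, 12 m 0 and 0, 18 m 0 and 1, and 30 m 0 and 0.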
